A study of Mus musculus with 6 samples.

How the data were processed

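RNA-seq was done on 6 samples of YFP-positive cells sorted from the mouse subventricular zone, 3 of the THC and 3 of the TKO genotype. Per the labels' protocols, total RNA was isolated with a PicoPure kit and kept at an RNA quality number of at least 8.0, and at least 35 ng was converted to cDNA with the SMART-Seq v4 kit and made into libraries with the Nextera XT kit. This chemistry does not keep the strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Groups, replicate numbers and batches were taken from the titles, genotypes and batch labels. The series text calls the samples biological replicates, and each was a pool of several mice.

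The submitters' processing notes name HISAT2, featureCounts from Subread, DESeq2 and the genome build GRCm38. Their versions, the gene annotation, the read filters and the treatment of reads that map to several genes are not given in the sources used here. Genes with close copies, such as H2-K1 and H2-D1, Hspa1a and Hspa1b, or Tubb6 and other tubulins, are therefore uncertain to the extent that reads were shared between them. The authors' deposited table holds, for 55487 genes, a normalized count per sample, which is a signal scaled by 1 factor per sample. Every value in a deposited column was a whole multiple of a step (0.944 to 1.07), within 0.001 of a read, for 100% of values. The steps equalled the inverse of median-of-ratios size factors to within 2.75e-11 of their value. Dividing by the step gave 15536084 to 16961817 reads per library, which is the depth quoted in the results. Per the file headers, the authors' deposited table also holds the mean normalized count, the log2 fold change with its standard error, a Wald score, an unadjusted p-value, an adjusted p-value and a weight per gene, a score used in independent hypothesis weighting. The deposited log2 fold changes are TKO over THC. Of the genes, 12197 had a weight of 0 and an adjusted p of 1, and 6 of these would be called by Benjamini-Hochberg adjustment of the deposited p (median mean normalized count 3.94).

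No pair of libraries was a duplicate: chi-square per degree of freedom between libraries of a genotype was 15.6 to 44.1. Of the genes, 23469 had no reads in any sample, and 114 symbols were shared by more than 1 gene. Coordinates were taken from GENCODE M21 (GRCm38, the same build) by gene identifier, which matched 17263 of the 17278 genes tested. They are the spans of whole genes, exons and introns included. No column of sample values was left unmapped.

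The plan, fixed before the data were examined, foresaw a count test if the table held counts and limma on log2(value + 1) if it held normalized values. The table holds normalized values, so limma (version 3.58.1, R 4.3.3) was used, with an intensity trend and a design of batch plus genotype. Genes were kept where the normalized count was at least 10 in at least 3 samples. The model had 3 residual degrees of freedom and 8.90 prior degrees of freedom. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 17278 genes, and a gene was called at an adjusted p under 0.05. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. Means and SDs are of normalized counts over the 3 samples of a genotype. Within February there is 1 sample per genotype, so its difference has no test.

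Before the data were examined, 21 gene lists with 763 genes were fixed. All 763 matched a gene of the table, 5 of them through another symbol, and 2 had more than 1 row. Lists share some members, such as Cdkn1a in the Rb-E2F and p53 lists. Members were counted as higher or lower over all genes tested and adjusted over the list alone. The set test was camera of limma with a preset correlation of 0.01, adjusted over the 21 lists, beside camera with an estimated correlation and fry. camera compares the list with all other genes, and fry tests whether the genes of a list move, on balance, 1 way. The estimated correlation comes from the residuals of 6 libraries, with 3 residual degrees of freedom.

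The genes named were those of a rule fixed before the data were examined: the targeted genes, a panel of 10 genes (among them E2f1, E2f3, Ccne1, Cdkn1a, Egfr, Mki67, Gfap, Dcx and Sox2), the 4 largest rises and 4 largest falls, and 2 members per list. Rises and falls were ranked among called genes with non-overlapping groups, a mean normalized count of at least 100 and an official name. The members of a list were those with the smallest adjusted p. Other members were picked as examples after their values were seen. A gene of the panel is not reported here.

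The test was checked on simulated data with 17400 genes, in which limma recovered 23.9% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 100% of those changed 4-fold. There 2 unchanged genes were called, 1.50% of calls. The simulation changed 67, 67 and 66 genes at these folds, with no batch difference, whereas 4814 genes were called in the data. Fewer changed genes make the Benjamini-Hochberg threshold stricter, so these shares need not hold for the data. Small changes may still be missed with 3 samples per genotype. Alternatives were other pseudocounts, other filters, no batch term, the replicate number as a block, the November samples alone, each sample left out in turn, other scalings and limma without the trend. The count-based tests foreseen in the plan were not run. The rule applied to accept reads as recovered refuses columns whose step lies close to 1, as in THC 1 (1.002) and THC 3 (1.01), so these columns were kept as normalized values like the others. For the closing section, 4 further gene lists were chosen after the data were seen.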

Results

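Gene expression was measured by RNA-seq in cells sorted from the subventricular zone (SVZ) of adult mice, the niche along the lateral ventricles that holds neural stem cells. The mice carried an inducible Cre recombinase driven by Nestin regulatory sequence and a YFP reporter at the Rosa26 locus, so that tamoxifen starts recombination and marks the cells in which it took place. The comparison was between 2 genotypes of the retinoblastoma family, whose members pRb, p107 and p130 bind E2F transcription factors and restrain cell-cycle genes. TKO mice had F/F alleles of Rb and p130 and no intact copy of p107, and THC mice were heterozygous at all of these loci. Tamoxifen was given at 200 mg/kg per day for 5 days from an age of 6 to 10 weeks, and tissue was taken 10 days after the last dose. Each sample was a pool of several mice with at least 200000 YFP-positive cells. There were 3 THC and 3 TKO samples, which the series calls biological replicates, and the background strain was mixed (C57BL/6 and Sv/129). A February batch held 1 sample of each genotype and a November batch held 2 of each.

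Depth was similar across libraries. Between 15536084 and 16961817 reads per library were assigned to genes, and 16858 to 17513 genes reached a normalized count of 10. Mitochondrial genes took 0.883 to 1.13% of the normalized counts in THC and 0.815 to 1.13% in TKO, and the 10 most abundant genes of a library took 3.60 to 4.35%. Spearman correlations across genes were 0.974 to 0.988 within genotypes and 0.942 to 0.958 between them. Xist, the RNA of the inactive X chromosome of female cells, had no reads in TKO 1 and a normalized count of 944 to 2047 in the other libraries. The Y-linked gene Ddx3y was at 510.0 to 1896 in all 6 libraries.

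The targeted genes were examined first. Rbl1, which encodes p107 (chromosome 2, 157145893 to 157204534, GRCm38), had a normalized count of 554 ± 80.5 in THC and 24.9 ± 14.9 in TKO (SD, n = 3 each). It fell by 4.56 on the log2 scale (SE 0.31, adjusted p = 2.3e-06), and every TKO library lay below every THC library. Rb1 (chromosome 14, 73183673 to 73325822) was at 1849 ± 199 in THC and 3267 ± 355 in TKO, a rise of 0.82 (SE 0.13, adjusted p = 0.00066). Rbl2, which encodes p130 (chromosome 8, 91070057 to 91123844), was at 1042 ± 202 and 939.5 ± 32.9, with a log2 change of -0.13 (SE 0.14, adjusted p = 0.54), and 0.02 within the November batch. Counts of Rb1 and Rbl2 were made over the whole gene and the floxed part is not given in the labels, so for these genes the counts check neither recombination nor the label. The Rbl1 counts fit the p107 genotype of all 6 libraries.

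In TKO, nearly all measured members of the G1/S and DNA replication list and of the G2/M and mitosis list were higher, as were most interferon-stimulated genes. Most genes of the lists for quiescent stem cells and astrocytes, for neuroblasts and for the oligodendrocyte lineage were lower. Mki67, the proliferation marker Ki-67, rose 3.44-fold, Cdkn1a, the inhibitor p21, rose 5.63-fold, and the chemokine gene Cxcl10 rose 27.6-fold. Among 17278 genes tested, 2469 were higher and 2345 were lower in TKO at an adjusted p under 0.05, which is 27.9% of the genes. Of these, 1274 were higher and 919 were lower by at least 2-fold, and the median log2 change was 1.03 among the higher genes and -0.84 among the lower genes. The 3 TKO values did not overlap the 3 THC values for 6717 genes (38.9%, where chance gives 10%). Among the called genes the direction was the same within the February pair for 99.3% and within November for 100%. The reported change is a weighted mean of the February and November differences, so for called genes this agreement follows largely from their selection. The first principal component, with 55.3% of the variance, separated the genotypes, and the second, with 17.7%, separated February from November.

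**Figure D1:**
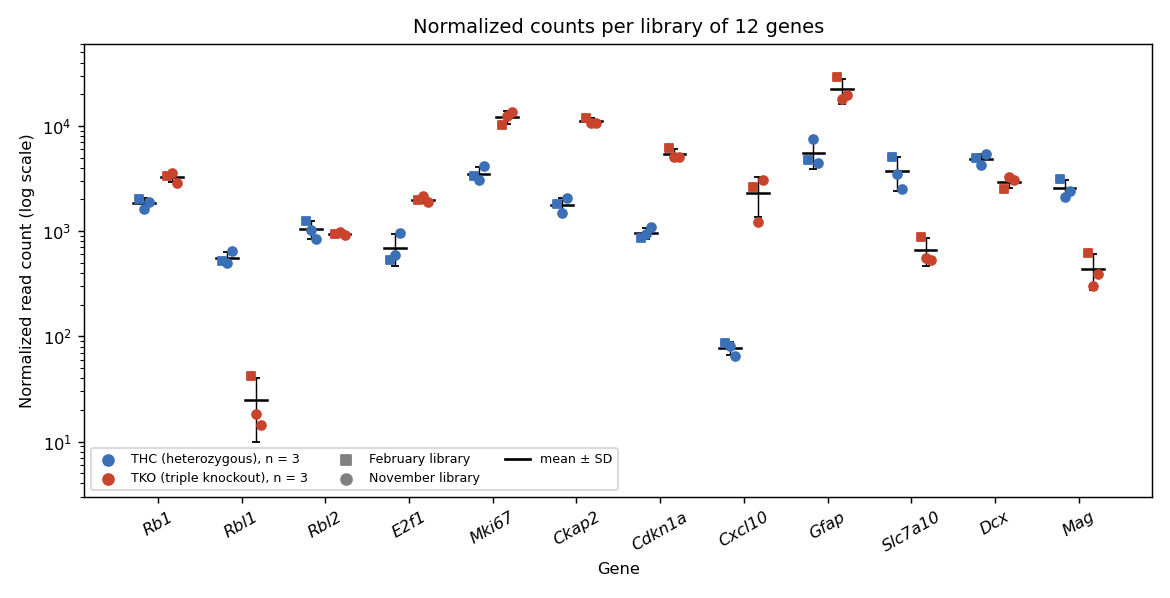
Normalized read counts of 12 genes (log axis) in the 3 THC and 3 TKO libraries, with squares for February, circles for November and bars for mean ± SD. Rbl1 falls from 554 to 24.9 in the mean and Ckap2 rises from 1785 to 11062, while the Rbl2 values of both genotypes overlap.

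The S-phase and mitotic programmes rose almost as a whole. In the description of gene lists, members outside the naming rule were picked as examples after their values were seen. Of 54 G1/S and DNA replication genes, 52 rose and none fell (53 and none adjusted over the list alone), with a median log2 change of 1.34 (1.498 in February, 1.27 in November). Pole, the catalytic subunit of DNA polymerase epsilon, rose by 1.74 (SE 0.12, adjusted p = 2.2e-06) from 816 ± 80.2 to 2718 ± 43.0. Uhrf1, a factor of maintenance DNA methylation, rose by 1.79 (SE 0.14, adjusted p = 4.4e-06), and Cdt1 and Cdc6, which license replication origins, rose by 2.11 and 1.90. Fen1 (0.58) did not pass. All 60 G2/M and mitosis genes rose, over all genes tested and adjusted over the list alone, with a median of 1.54 (1.62 in February, 1.51 in November). The spindle genes Ckap2 and Aspm rose by 2.64 (SE 0.14, adjusted p = 9.5e-07) and 1.81 (SE 0.13, adjusted p = 2.7e-06), and Mki67 rose by 1.78 (SE 0.15, adjusted p = 7.1e-06). camera gave adjusted p = 8.5e-34 for the G1/S list and 3.1e-42 for the G2/M list with its preset correlation, and adjusted p = 0.27 for each with an estimated correlation.

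Of 33 measured members of the Rb-E2F network and cell-cycle regulator list, 24 rose and 2 fell, also when adjusted over the list alone, with a median of 0.67 (0.71 in February, 0.69 in November). E2f1 rose from 698 ± 237 to 1996 ± 127, by 1.56 (SE 0.18, adjusted p = 5.7e-05), and E2f7, E2f8 and Mybl1 rose by 2.00, 2.34 and 3.24. The inhibitor genes rose with them: Cdkn1a by 2.49 (SE 0.14, adjusted p = 9.5e-07) and Cdkn2c, which encodes p18, by 2.52 (SE 0.16, adjusted p = 1.8e-06). Ccnd2 and Cdk6, a D-type cyclin and a kinase it activates, fell (-1.14 and -0.90), and Ccnd1 (-0.05), Cdk4 (0.03) and E2f4 (0.08) did not pass. E2f3 was at 344 ± 74.8 and 485 ± 67.1, a log2 change of 0.51 (SE 0.18, adjusted p = 0.0498). That call ended in most other settings, including without THC 2 (adjusted p = 0.098), THC 3 (0.16), TKO 2 (0.24) or TKO 3 (0.084). Ccne1, cyclin E1, had a change of 0.62 (SE 0.18, adjusted p = 0.026), which did not pass without THC 1 (0.49, adjusted p = 0.12), THC 2 (0.50, 0.094), TKO 1 (0.49, 0.13) or TKO 2 (0.58, 0.087). Of 38 DNA repair genes, 34 rose and none fell, also adjusted over the list alone, with a median of 1.39 (1.45 in February, 1.23 in November). Brca1 and the DNA glycosylase gene Neil3 rose by 1.87 (SE 0.12, adjusted p = 1.8e-06) and 1.95 (SE 0.14, adjusted p = 2.7e-06), and Parp1 (0.23) and Xrcc5 (-0.10) did not pass. camera gave adjusted p = 7.9e-11 for the network list and 1.2e-21 for the repair list, and adjusted p = 0.27 for each with an estimated correlation.

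Genes of quiescent neural stem cells and astrocytes moved the other way. Of 48 genes, 29 fell and 3 rose (32 and 3 adjusted over the list alone), with a median of -0.65 (-0.84 in February, -0.60 in November). The amino acid transporter gene Slc7a10 fell from 3709 ± 1298 to 659 ± 197 (log2 change -2.47, SE 0.14, adjusted p = 1.0e-06). The neurotensin receptor gene Ntsr2 (-2.38, SE 0.18, adjusted p = 3.6e-06), Aldoc (-2.35) and Id2 (-0.89), Id3 (-0.61) and Id4 (-0.67) fell as well, while Id1 of the Notch and BMP list rose by 0.46. The list did not move as a unit. Gfap, the intermediate filament of astrocytes and SVZ stem cells, rose from 5563 ± 1679 to 22226 ± 5928, by 2.01 (SE 0.23, adjusted p = 4.7e-05), and Mt2 and Prom1 rose by 0.97 and 0.51. Sox9 (-0.01), Slc1a3 (0.00) and Vcam1 (-0.10) did not pass. camera gave adjusted p = 7.9e-11, and adjusted p = 0.42 with an estimated correlation.

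Of 28 genes of activated stem cells and transit-amplifying progenitors, 6 rose and 5 fell (8 and 5 adjusted over the list alone), and the list did not pass (median 0.14, camera adjusted p = 0.45, and adjusted p = 0.88 with an estimated correlation). Its median was -0.09 in February and 0.11 in November, and -0.05 without TKO 2. Those that rose included Fbxo5, an inhibitor of the anaphase-promoting complex (1.34, SE 0.14, adjusted p = 3.0e-05), and Nes, the intermediate filament nestin (1.21, SE 0.14, adjusted p = 6.7e-05). Ccnd2, Lima1, Miat, Dlx1 and Rgcc fell. Egfr had a change of 0.20 (SE 0.16, adjusted p = 0.39), with -0.31 in February and 0.46 in November. Sox2 had a change of 0.37 (SE 0.13, adjusted p = 0.056). Without THC 1 or TKO 1, which leaves only the November samples to set the difference, Sox2 passed at 0.49 (adjusted p = 0.043 in each case). In the February pair the change of Sox2 was 0.13.

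Neuroblast genes fell. Of 41 genes, 27 fell and none rose (30 and none adjusted over the list alone), with a median of -0.54 (-0.66 in February, -0.53 in November). Dcx, the microtubule-associated protein of migrating neuroblasts, fell from 4884 ± 551 to 2944 ± 392 (log2 change -0.73, SE 0.14, adjusted p = 0.0022). Stmn4 (-1.32, SE 0.13, adjusted p = 1.4e-05), Runx1t1 (-1.20, SE 0.14, adjusted p = 7.4e-05), Tubb3 (-1.04) and Gad1 (-0.94) fell as well. camera gave adjusted p = 3.3e-12, and adjusted p = 0.27 with an estimated correlation. Of 23 measured striatal and mature neuron genes, 5 fell and 1 rose, also adjusted over the list alone (median -0.34, -0.29 in February and -0.28 in November, and -0.13 without TKO 2). This list did not pass (camera adjusted p = 0.16, and adjusted p = 0.46 with an estimated correlation). The synaptic gene Snap25 fell by 0.91 (SE 0.15, adjusted p = 0.00085), Ppp1r1b, which encodes DARPP-32 of striatal projection neurons, fell by 1.20 (SE 0.21, adjusted p = 0.0011), and Pdyn rose by 2.19.

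Markers of other cells of the niche differed between the genotypes too. Of 26 oligodendrocyte lineage genes, 16 fell and none rose (17 and none adjusted over the list alone), with a median of -1.49 (-1.51 in February, -1.48 in November). The myelin genes Mag and Opalin fell, with log2 changes of -2.59 (SE 0.14, adjusted p = 9.6e-07) and -2.52 (SE 0.17, adjusted p = 2.2e-06), as did Mbp (-1.77). The progenitor genes Pdgfra (0.42) and Cspg4 (0.24) and the lineage factors Olig1 (-0.03) and Sox10 (0.00) did not pass. Of 33 endothelial and mural genes, 22 fell and 1 rose (25 and 1 adjusted over the list alone), with a median of -1.18 (-0.61 in February, -1.42 in November, and -0.77 without THC 2). Pdgfrb, a pericyte receptor, fell by 1.32 (SE 0.16, adjusted p = 9.8e-05), the tight junction gene Cldn5 fell by 1.64 (SE 0.22, adjusted p = 0.00019), and Col1a2 rose by 0.74. camera gave adjusted p = 1.5e-11 for the oligodendrocyte list and 7.5e-09 for the endothelial list, and adjusted p = 0.27 and 0.42 with an estimated correlation. The endothelial list did not pass by fry (adjusted p = 0.12).

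Of 27 measured microglia and macrophage genes, 10 rose and none fell (13 and 1 adjusted over the list alone), with a median of 0.88 (0.65 in February, 1.05 in November, and 0.59 without TKO 2). Fcrls and Cd68 rose by 1.48 (SE 0.33, adjusted p = 0.0052) and 0.88 (SE 0.21, adjusted p = 0.0084). Their levels differed more by batch than by genotype. Fcrls was at 344 in THC 1 and 755 in TKO 1, and at 20.2 to 124 in the November libraries. camera gave adjusted p = 0.00010, adjusted p = 0.46 with an estimated correlation and adjusted p = 0.12 by fry, and with no batch term neither the list (adjusted p = 0.090) nor either gene passed. Of 30 measured ependymal genes, 4 fell and 2 rose (4 and 1 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.45, and adjusted p = 0.89 with an estimated correlation). The direction differed between batches, with a median of 0.91 in the February pair and -0.60 in November. Without THC 1 or TKO 1 the list was lower (median -0.60, adjusted p = 9.2e-08 and 1.9e-07), and without THC 2 or TKO 2 its median was 0.09 and 0.20. Ccdc39, a gene of the ciliary axoneme, rose by 0.61 (SE 0.14, adjusted p = 0.0066), and did not pass without THC 1 (0.46, adjusted p = 0.057) or TKO 1 (0.46, adjusted p = 0.061). Rarres2 fell by 1.02 (SE 0.25, adjusted p = 0.0085), with -0.02 in February and -1.52 in November, and did not pass with no batch term (adjusted p = 0.054).

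**Figure D2:**
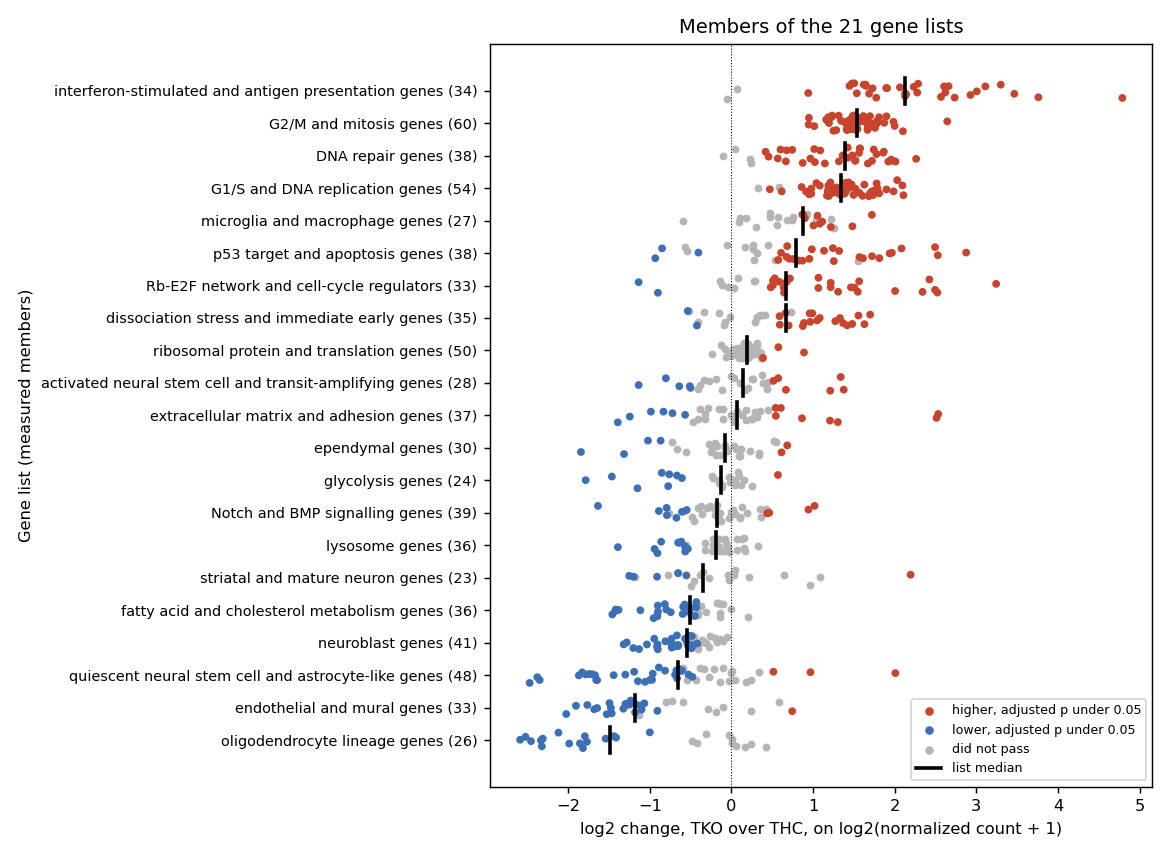
Log2 change (TKO over THC) of each measured member of the 21 gene lists, with red for higher, blue for lower and grey for genes that did not pass, and a black bar at the list median. Medians run from -1.49 for oligodendrocyte lineage genes to 2.13 for interferon-stimulated genes, and all 60 G2/M genes lie to the right of 0.

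Interferon-stimulated and antigen presentation genes had the highest median of the 21 lists. Of 34 genes, 32 rose and none fell, also adjusted over the list alone, with a median of 2.13 (2.09 in February, 2.11 in November). Cxcl10 rose from 77.4 ± 11.3 to 2303 ± 952, by 4.79 on the log2 scale (SE 0.27, adjusted p = 9.6e-07). Usp18, a protease that removes ISG15, rose from 128 ± 39.7 to 1432 ± 469, by 3.46 (SE 0.19, adjusted p = 9.5e-07). The immunoproteasome genes Psmb8 and Psmb9 rose by 3.30 and 2.73, and B2m, the light chain of MHC class I, by 2.13. Tap2 (0.06) and Sting1 (-0.05) did not pass. The median of the microglia list rose beside it, by 0.88. camera gave adjusted p = 8.9e-25, and adjusted p = 0.27 with an estimated correlation.

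Of 38 p53 target and apoptosis genes, 24 rose and 3 fell (28 and 5 adjusted over the list alone), with a median of 0.79 (1.04 in February, 0.82 in November). Beside Cdkn1a, the death receptor gene Eda2r rose by 2.53 (SE 0.16, adjusted p = 1.8e-06), and Pmaip1 and Bbc3, which encode the pro-apoptotic proteins Noxa and Puma, rose by 2.87 and 1.61. Sesn1, Perp and Ercc5 fell (-0.93, -0.85 and -0.40). Of 35 dissociation stress and immediate early genes, 19 rose and 2 fell (22 and 3 adjusted over the list alone), with a median of 0.66 (0.79 in February, 0.53 in November). The transcription factor genes Egr2 and Nr4a1 rose by 1.27 (SE 0.12, adjusted p = 1.4e-05) and 1.48 (SE 0.18, adjusted p = 9.2e-05). The heat shock gene Hspa1b and Btg1 fell (-0.54 and -0.42), and Jun (0.31), Fosb (0.37) and Dusp1 (-0.02) did not pass. camera gave adjusted p = 5.0e-10 for the p53 list and 2.5e-06 for the stress list, and adjusted p = 0.27 and 0.40 with an estimated correlation.

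Of 36 fatty acid and cholesterol metabolism genes, 23 fell and none rose (28 and none adjusted over the list alone), with a median of -0.51 (-0.63 in February, -0.50 in November). The fatty acid synthesis genes Fasn (-0.10) and Acaca (0.21) did not pass. The cholesterol synthesis genes Msmo1 and Dhcr7 fell, with log2 changes of -1.38 (SE 0.15, adjusted p = 3.0e-05) and -1.12 (SE 0.12, adjusted p = 4.2e-05). Of 24 glycolysis genes, 8 fell and 1 rose, also adjusted over the list alone (median -0.13, -0.17 in each batch, and -0.02 without THC 2). Aldoa fell from 11230 ± 1550 to 3257 ± 463 (-1.79, SE 0.15, adjusted p = 5.7e-06). Pdk2, a kinase that inhibits pyruvate dehydrogenase, fell by 1.15 (SE 0.13, adjusted p = 5.7e-05), and Tpi1 rose by 0.57. Of 36 lysosome genes, 10 fell and none rose, also adjusted over the list alone (median -0.19, -0.16 in February and -0.23 in November, and -0.11 without THC 2). Neu1 and Ctsa, whose products form a complex, fell, with changes of -1.39 (SE 0.17, adjusted p = 7.3e-05) and -0.86 (SE 0.14, adjusted p = 0.00062). camera gave adjusted p = 1.6e-10, 0.0087 and 0.00081 for these lists in that order, and adjusted p = 0.27, 0.42 and 0.56 with an estimated correlation. By fry the lysosome list did not pass (adjusted p = 0.12).

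The remaining lists moved little or in both directions. Of 50 ribosomal protein and translation genes, 3 rose and none fell (1 and none adjusted over the list alone), with a median of 0.19 (0.15 in February, 0.20 in November). camera gave adjusted p = 0.010, adjusted p = 0.76 with an estimated correlation and adjusted p = 0.46 by fry. The median was 0.07 without THC 2 (adjusted p = 0.41), 0.06 without TKO 2 (adjusted p = 0.36) and 0.29 without TKO 3. Nop58, a core protein of box C/D small nucleolar RNPs, rose by 0.89 (SE 0.15, adjusted p = 0.0011). Rps19 rose by 0.57 (SE 0.16, adjusted p = 0.017), and did not pass without THC 2 (adjusted p = 0.072) or TKO 2 (adjusted p = 0.087). Of 39 Notch and BMP signalling genes, 7 fell and 4 rose, also adjusted over the list alone (median -0.17, -0.12 in February and -0.20 in November, and -0.05 without THC 2, camera adjusted p = 0.28, and adjusted p = 0.70 with an estimated correlation). The Notch target Heyl fell by 1.63 (SE 0.27, adjusted p = 0.00086), while Hes1 rose by 0.94 and the BMP antagonist gene Chrdl1 by 1.02 (SE 0.16, adjusted p = 0.00059). Of 37 measured extracellular matrix and adhesion genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone). The median was 0.06, with -0.05 in February and 0.15 in November, and -0.02 without THC 3 and -0.01 without TKO 3 (camera adjusted p = 0.58, and adjusted p = 0.89 with an estimated correlation). Cd44, a hyaluronan receptor, rose by 2.53 (SE 0.19, adjusted p = 3.8e-06), and Ncan, the proteoglycan neurocan, fell by 1.39 (SE 0.15, adjusted p = 3.0e-05). Across all 21 lists, 16 passed with the preset correlation, 12 by fry and 0 with an estimated correlation. With an estimated correlation, 2 of the 16 had an unadjusted p under 0.05, the oligodendrocyte list (p = 0.013) and the p53 list (p = 0.037).

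**Figure D3:**
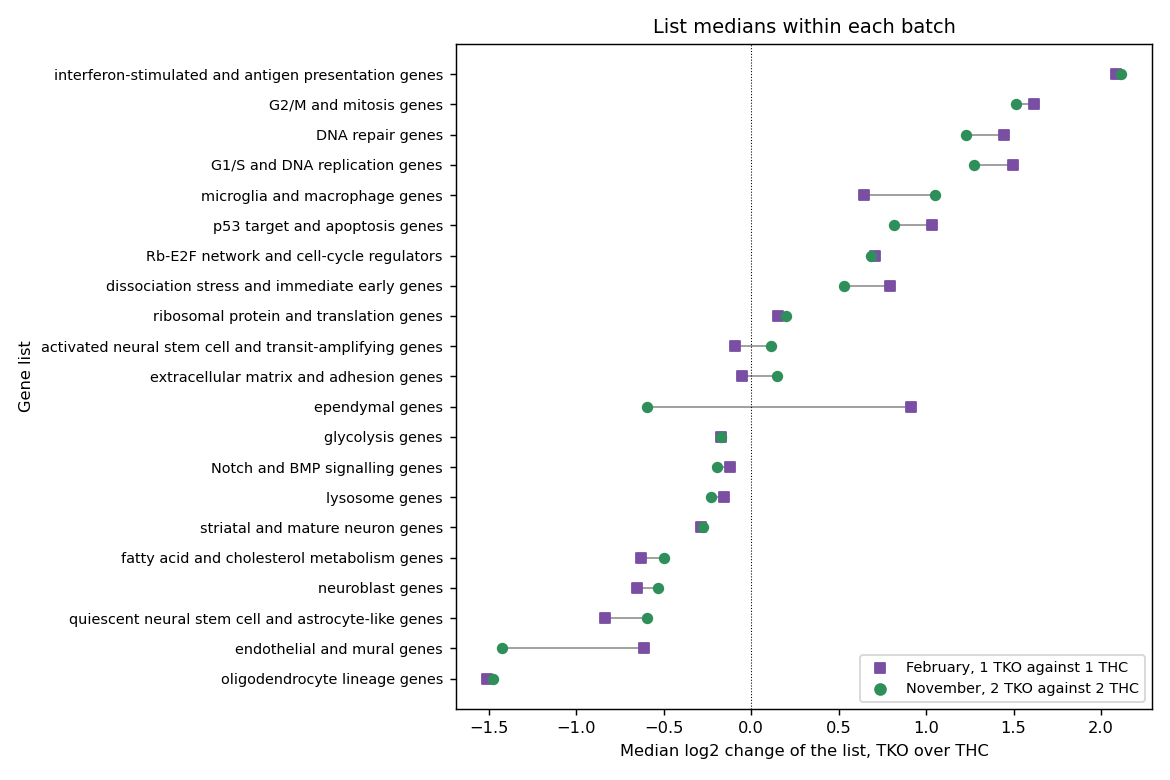
Median log2 change (TKO over THC) of each of the 21 lists within the February pair (squares, 1 sample per genotype) and within November (circles, 2 per genotype). The ependymal list lies at 0.91 in February and -0.60 in November, whereas the interferon list lies at 2.09 and 2.11.

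The genes with the largest rise under the naming rule were Otoa, Serpinb8, Ifi27l2a and Tubb6. Otoa, which encodes otoancorin of the inner ear (chromosome 7, 121081650 to 121163097), went from 3.64 ± 2.92 to 273 ± 85.5, a log2 change of 6.01 (SE 0.37, adjusted p = 1.4e-06). The serpin gene Serpinb8 (chromosome 1, 107590006 to 107610484) went from 36.9 ± 5.00 to 1250.1 ± 65.0, a change of 5.05 (SE 0.19, adjusted p = 4.8e-08). Ifi27l2a (chromosome 12, 103442167 to 103443680), an interferon-induced gene, rose by 4.98 (SE 0.36, adjusted p = 3.0e-06). The beta-tubulin gene Tubb6 (chromosome 18, 67390717 to 67402749) rose by 4.86 (SE 0.13, adjusted p = 2.6e-09) from 139 ± 5.12 to 4118 ± 775, the smallest p of all genes tested. After Rbl1, the largest falls were those of Etnppl, Fam163a and Prokr2. Etnppl, an astrocytic phospho-lyase gene (chromosome 3, 130617448 to 130637521), fell from 683 ± 242 to 50.6 ± 15.2 (-3.71, SE 0.24, adjusted p = 1.8e-06). Fam163a (chromosome 1, 156075966 to 156205026) fell by 3.20 (SE 0.34, adjusted p = 3.4e-05). Prokr2, a receptor for prokineticins that guide neuroblasts to the olfactory bulb (chromosome 2, 132337733 to 132385447), fell by 3.03 (SE 0.20, adjusted p = 2.2e-06) from 1556 ± 689 to 179 ± 46.3. Changes of low genes such as Otoa are understated on the log2(value + 1) scale.

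Fewer genes were called between the batches than between the genotypes. The batch comparison sets 2 February against 4 November samples, so the counts are not of equal power. In the same model, 10 genes were higher and 100 lower in November than in February. This count depended on single libraries: it was 49 without THC 1, 425 without TKO 1 and 53 without TKO 3.

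In the authors' deposited table, 4817 of 32018 genes with a p had an adjusted p under 0.05, of which 2459 were higher and 2358 lower in TKO. Of the calls in the authors' deposited table, 4606 were also called here, all in the same direction, 183 were tested here and did not pass, and 28 were not tested here because of the filter. Another 208 genes were called here and not in the authors' deposited table. The log2 changes in the authors' deposited table were 0.82 for Rb1 (adjusted p = 5.4e-07), -4.56 for Rbl1 (adjusted p = 4.3e-44) and -0.14 for Rbl2 (adjusted p = 0.67). Rarres2 did not pass in the authors' deposited table (-1.03, adjusted p = 0.068). Benjamini-Hochberg adjustment of the unadjusted p in the authors' deposited table gave 4261 calls, 2201 higher and 2060 lower.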

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

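Scaling to equal totals, scaling to equal upper quartiles and limma without the trend were chosen after the data were seen; the other settings were planned. In the settings run, no gene called in the reported fit and still tested changed sign. Other filters, no batch term, the replicate block and limma without the trend leave the log2 changes as they are. No sign could change in those settings. Calls were 2429 higher and 2293 lower with a pseudocount of 0.1, 2521 and 2383 with 5, 2279 and 2009 with no filter, 2162 and 2197 with at least 1 CPM in all 6 samples, 2065 and 1865 with no batch term, 1869 and 1981 in November alone, 2379 and 2392 at equal totals, and 2473 and 2293 at equal upper quartiles. Without the trend they were 1806 and 1484. Leaving out each library in turn gave 1793 to 2215 higher and 1600 to 2031 lower; a batch then holds 0 or 1 sample of that genotype, and a lone sample is assumed to vary like the others. The batch count of 110 became 64 with at least 1 CPM in all samples, 0 by limma without the trend (1812 at an unadjusted p under 0.05, against 2476 with it), and 49 to 425 over the fits without 1 library. The cause was not tested. With an estimated correlation camera lost the calls of the lists with medians 1.34 (G1/S), 1.54 (G2/M), -0.65 (quiescent), -0.54 (neuroblast), -1.49 (oligodendrocyte), 0.79 (p53) and 2.13 (interferon), at adjusted p = 0.27, and 0.42 for the quiescent list; the estimate itself replaced the preset value. Rbl2 turned to 0.016 in November alone and ranged from -0.25 to 0.016 without 1 library. Medians ranged over those fits from -0.60 to 0.20 for ependymal genes, -0.018 to 0.15 for matrix genes and -0.048 to 0.19 for activated stem cell genes. None of these 4 passed in the reported fit. Of 594 values of named genes in the other settings, 574 kept direction and side of the threshold, 16 lost the call and 3 gained it. Otoa and Ifi27l2a fell under the filter when a TKO library was left out, and had no value there. Count tests on recovered reads and TMM scaling were not run.

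With the replicate number as a replicate block in place of the batch term, 2147 genes were higher and 1922 lower, and 4041 of the 4814 calls were kept. Deviations from the genotype means correlated at 0.23, -0.11 and 0.14 between samples of the same number, so they did not follow the numbers throughout. These deviations still hold the batch difference and rest on few samples, so they cannot show whether the numbers pair the samples. THC 3 deviated most like TKO 2 (0.18).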

Other observations

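The tests of the multiciliation, germ cell and secreted factor lists, of microglia, of single libraries and of other cell types were chosen after the data were seen. The tests of scaling, linked loci and sample splits were set before their own results were seen, although the scalings used were added after the data were seen.

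Part of a list of early multiciliation genes rose in TKO. Of 19 early multiciliation genes, 13 rose and none fell, with a median log2 change of 0.97 (1.35 in February, 0.79 in November). Foxn4, a transcription factor, rose by 4.55 and Mcidas, which encodes the regulator multicilin, by 3.73. Ccno and Deup1, which acts in centriole amplification, rose by 1.41 and 1.70. Foxj1 (0.54), Trp73 (0.27), Rfx2 (0.49), Rfx3 (0.20) and Ccdc78 (-0.47) did not pass. Cdc20b had no reads in THC and was at least 19.1-fold higher in TKO against a floor of 3 counts over the group. Mcidas, Ccno and Cdc20b are neighbours on chromosome 13. camera gave p = 8.9e-08 for the list (adjusted p = 3.6e-07 over the 4 further lists), which did not hold with an estimated correlation (p = 0.038, adjusted p = 0.12). The median stayed between 0.67 and 1.10 in the fits without 1 library. Foxn4, Mcidas and Cdc20b passed the filter only through their TKO values. The median and the camera p thus cover members that the rise itself helped to admit. Plk4, Stil, Sass6, Cep152, Tfdp1, E2f5 and Myb, which are among the 13, also serve cycling cells, so the list does not tell the programmes apart.

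Part of a germ cell list rose. Of 40 genes, 21 could be tested, of which 11 rose and 1, Mlh3, fell, with a median of 1.27 (camera p = 2.2e-05, adjusted p = 3.0e-05, and adjusted p = 0.12 with an estimated correlation). Rbm44 rose by 5.40 and Stag3, a meiotic cohesin subunit, by 1.91, while the germ cell markers Dazl (-0.26), Ddx4 (-0.93) and Sycp2 (-1.21) did not pass. Rbm44, Meiob, Meioc and Tex11, which rose, passed the filter only through their TKO values. The median and the camera p therefore cover members that the rise itself helped to admit. The 28 measured senescence-associated secreted factor genes had 17 that rose and 4 that fell, with a median of 1.64 (1.10 in February, 1.61 in November; camera p = 1.0e-06, adjusted p = 2.0e-06, and adjusted p = 0.18 with an estimated correlation). Il6 rose by 4.89 and Gdf15 by 4.83, while Cxcl12 and Vegfa fell. Il6, Gdf15, Areg, Cxcl2, Lif and Il1b, which rose, had fewer than 3 THC values of at least 10, so TKO values helped them pass the filter. The median and the camera p of this list cover these members too. Microglia express part of this list: Il1b was at 165 in THC 1 and 731 in TKO 1, and at 8.08 to 157 in November. These lists were drawn up because single members stood out, so each result is a hypothesis that may not hold in other samples.

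The rise of the interferon list could come from more microglia and macrophages in the TKO sorts. The YFP gate should remove most of these cells, but this was not checked. Of 17 abundant microglial genes, all of them also in the microglia list, 7 rose and none fell (median 0.90, limma camera adjusted p = 0.0012 over the 4 further lists, which does not hold with an estimated correlation, p = 0.36, or by fry, p = 0.13), and C1qb, among the most abundant, was at 64.6 to 1193 and higher in the February library of each genotype. Their median differed from that of the interferon list by -1.23 (95% bootstrap interval over genes -1.73 to -0.82). That interval treats genes as independent and holds no spread between pools. The lowest median of the interferon list in the February pair and in the fits without 1 library was 1.87. These values argue against more microglia with unchanged expression, and against a single batch or library, as the whole cause. The 17 genes were chosen for microglia, so more macrophages, or microglia with changed expression, were not tested. A response of the knockout cells themselves, or of a different kind of cell in the sort, stays open and was not tested.

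The fall of oligodendrocyte lineage and endothelial genes could come from fewer cells of every other type in the TKO sorts. In that case the markers of all other types would fall alike. The microglia list lay 2.06 above the endothelial list (95% bootstrap interval over genes 1.76 to 2.25), the ependymal list 1.10 and the striatal list 0.84. These lists thus did not fall alike with the endothelial list, and the oligodendrocyte list was not compared in this way. Microglial levels differed more by batch than by genotype, and the ependymal median was 0.91 in February and -0.60 in November. Fewer cells of every other type is therefore not excluded. Scaling to equal totals or upper quartiles left the oligodendrocyte and endothelial medians at -1.18 or lower. These scalings moved log2 changes by a median of -0.011 and 0.0045, too little to bring such medians near 0. The YFP gate should remove most endothelial cells, but this was not checked. In THC, Itm2a was at 4777 ± 2684 and Slco1a4 at 2720 ± 1471, beside 4884 ± 551 for Dcx, while Cldn5 (603) and Cdh5 (112) were lower. Endothelial transcripts were thus present in the sorts. A loss of these types alone, in the tissue or in the sort, and a change of expression within them stay open and were not tested.

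Genes linked to the targeted alleles can differ between genotypes because of the mixed strain background. Among the 100 called genes of largest change with coordinates, 3 lay within 10 Mb of a targeted gene, against 2.98% of all genes tested (odds ratio 1.01, 95% interval 0.20 to 3.04, one-sided Fisher exact p = 0.58), too few to decide. Over all tested genes, 33.0% of the 515 near genes were called and 27.7% of the others (odds ratio 1.29, two-sided Fisher exact p = 0.0094). The Fisher test treats genes as independent, whereas the near genes are neighbours around the targeted genes. Its p holds no spread between stretches of the genome. The 3 genes, 9330175E14Rik, Misp3 and Ces1g, all lie near Rbl2 on chromosome 8, and Ces1g had no reads in THC and was at 10.8 to 21.5 in TKO. Linked sequence stays open for them and for the other near genes among the 170 called. Those include genes named above, such as E2f1 and Ctsa near Rbl1 and Stmn4 near Rb1.

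The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By limma the real split called 4814 genes and the highest of the other splits 0, where 67 to 635 genes had an unadjusted p under 0.05 against 6633 in the real split. Only 1 of the 10 splits, the real one, reached its count. Each other split mixed the genotypes, so the genotype difference added to its residual spread and held down its calls. The contrast of 4814 with 0 is therefore no measure of chance.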
